A study of Homo sapiens with 6 samples.

How the data were processed

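SP and non-SP cells of the ovarian carcinoma line IGROV1 were isolated by Hoechst 33342 cell sorting, with 3 samples in each group. Per the labels' protocols, RNA was isolated with a kit for small samples, amplified by whole-transcriptome amplification for picogram amounts and labelled with biotin. Such amplification widens the spread of weakly expressed transcripts, and the sort added a dye and laser exposure to both groups. SP cells are those that keep little of the dye. An effect of retained dye therefore cannot be told apart from other differences between the groups. The deposited values are log2 expression per probe set; per the submitters' processing notes, R 2.8.1, affy and RMA were used. RMA adjusts background, sets all arrays to 1 shared distribution of values and summarises the probes of a probe set, so that a global change in RNA content cannot be seen and differences near background are compressed. Further settings are not given in the sources used here. The first quartile per array lay between 3.90 and 3.93 and the third between 7.49 and 7.52, as in quantile-normalized data. For arrays, precision is limited by their number rather than by a read depth.

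The table held 54675 probe sets, of which 62 controls were left out of the tests. Of the 54613 others, 41091 carried 1 gene symbol in the platform annotation, 1801 carried several and 11721 were unnamed here. The single symbols were matched through Entrez ID to the RefSeq annotation of assembly GRCh38.p14 for 41037 probe sets, and 0 symbols changed; that annotation was used for names and for which genes neighbour each other, and no coordinates were used. For each of the 10523 genes with more than 1 probe set, the probe set with the highest mean over the 6 samples was used, whatever the group means. This gave 19775 genes, with no filter on dim ones. Probe sets of 1 gene can disagree: besides genes for which this is stated, FANCB, MRE11, ABCC11, SAMD9, SAMD9L, OAS1 and DHCR7 had at least 1 probe set of the other sign, some of them near background. With the mean of a gene's probe sets, 15 of the 53 named genes with several probe sets kept less than 50% of their difference, among them GNG11 (0.70), CARD16 (0.54), FANCB (0.28), MRE11 (0.24), ABCC11 (-0.12), SAMD9 (0.47), OAS1 (0.33), KIF20B (0.26) and DHCR7 (-0.06). The 13522 unnamed or multi-gene probe sets were tested apart.

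Differences are SP minus non-SP on the log2 scale. They were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior, no trend, no block), two-sided, over all 6 samples, and p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Intervals are at the 95% level from the same fit. Standard errors and adjusted p printed for genes are limma's. Gene lists (38 with at least 5 measured members, and 5 lists of markers of other cell types as a family of their own) were tested with camera at a preset inter-gene correlation of 0.01, again with Benjamini-Hochberg adjustment. Estimated correlations and fry were run as alternatives. Members of a list were also adjusted over the list alone. Control measures were compared by an exact permutation test. Python 3.11.15 and pandas 2.3.3 read the table, and figures were drawn with matplotlib 3.10.9.

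The grouping, tests, gene lists, alternatives and rule for named genes were fixed before the data were examined. The rule named the 12 genes with the highest and the 12 with the lowest difference among genes past the threshold with groups that do not overlap and a mean above the median level of 6.27; where fewer qualified, it went on in order of unadjusted p. It always named ABCG2, ABCB1, EZH2, PROM1, CD44, ALDH1A1 and KIT, and up to 4 members by p of each list described. Genes and array values outside the rule, such as LINC00518 as the single call, H2BC4, H2BC5, ASNS, RUNDC3B, CROT and DBF4, were chosen after their values were seen. The alternatives were a replicate block, the mean of a gene's probe sets, every probe set on its own, a filter on dim genes, cyclic loess, median centring, an intensity trend with a robust prior, array weights and leaving out each sample in turn. The array set as a block, the ACTB 3' minus 5' signal as a covariate and the Hoechst transporter list without ABCB1 were added after seeing the data. The array sets were read from the first principal component of all genes and are not groups of the study. Because they come from the values tested, p-values from fits with the set as a block may be too small.

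The fit was tested on simulated data with the real means and limma's moderated residual spread of 19775 genes, 200 of them changed, in 5 simulations. It recovered 59.4% of genes changed by 1 log2 unit, 92.8% of those changed by 2 and 99.7% of those changed by 4, with 37 false calls over the 5 simulations. A list shifted by 0.5 log2 units was called in 5 of 5 simulations and 1 other list was called. The simulated arrays carry no structure such as the array sets, and their genes vary independently of each other. The recovery is thus no measure of power in the real data, where ABCB1 at 4.78 and GJA1 at -4.29 were not called. Nor does it show how camera behaves on lists of correlated genes. The TrpnX probe sets, for a bacterial transcript, were taken as negative controls, since their mean lay below the first quartile of every array and the labels name no added transcript: for a gene at or below their mean on an array, that mean took the place of its level in the fold given as a lower bound. A first test of RNA integrity, which asked whether genes that differ between the array sets were shifted to 1 side, was dropped, because RMA centres the arrays and such genes are regulated together; the GAPDH 3' minus 5' signal took its place.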

Results

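IGROV1 is an established human ovarian carcinoma cell line. When such cells are stained with Hoechst 33342, a dye that binds DNA, a small fraction keeps little of the dye because membrane transporters pump it out, and these cells form the side population (SP) in flow cytometry. RNA was measured in sorted SP cells and in sorted cells outside that gate (non-SP), with 3 samples of each and no treatment other than the sort. Each sample was hybridised to 1 array, which gave log2 expression values for 54675 probe sets and, with 1 probe set per gene, for 19775 genes. The median log2 value per array lay between 5.59 and 5.64. The samples are described as biological replicates, but the labels do not say whether they came from separate cultures, so the p-values measure the spread between these samples, which may in part be technical. The number of arrays limits the precision of every difference below.

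The comparison of SP with non-SP cells asks which genes differ between cells that export the dye and cells that retain it. LINC00518, a long non-coding RNA gene, fell in SP cells, from a log2 level of 6.04 ± 0.15 (SD, n = 3) in non-SP cells to a measured 2.52 ± 0.15 (SD, n = 3) in SP cells, where it lay below the mean of the negative control probe sets (2.82 to 2.91) on all 3 arrays. Set against those controls it was at least 9.05-fold lower, with a measured log2 difference of -3.51 (SE 0.14) and lower values in 3 of 3 SP samples (limma, adjusted p = 0.00166). ABCB1, which encodes the drug efflux pump P-glycoprotein, a known exporter of Hoechst 33342, had a mean of 9.66 ± 0.91 (SD, n = 3) in SP cells and 4.89 ± 0.82 (SD, n = 3) in non-SP cells. The ABCB1 difference was 4.78 (SE 0.56), or 27.4-fold with a 95% confidence interval of 10.8 to 69.6, and all 3 SP values lay above all 3 non-SP values. The size depends on the probe set: the other ABCB1 probe set, also above the negative controls on all 6 arrays, differed by 2.45 (SE 0.43), or 5.48-fold. GJA1, which encodes the gap junction protein connexin 43, had a mean of 5.01 ± 0.64 (SD, n = 3) in SP cells and 9.30 ± 0.32 (SD, n = 3) in non-SP cells, a difference of -4.29 (SE 0.34).

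LINC00518 was the 1 gene of 19775 past an adjusted p of 0.05, so 1 gene was lower and 0 were higher in SP cells in this fit. At an unadjusted p under 0.05 there were 1340 genes, where chance at the nominal level gives 989. The groups did not overlap for 2350 genes (11.9%), where chance gives 10%. Parting the 6 samples into 3 and 3 in other ways, which mix SP and non-SP samples, gave 447 to 768 and 1254 to 1833 such genes. The exception was the split along the array sets described below, with 4143 and 5310 genes. ABCB1 had an adjusted p of 0.12 over all genes and 0.00119 adjusted over the list alone, the list being that of Hoechst and drug efflux. It passed over all genes with array weights (adjusted p = 0.038), with the array sets described below as a block (0.00142) and with the ACTB 3' minus 5' signal as a covariate (0.00332), which gave 4, 1 and 1 genes higher. These settings are not independent of each other. GJA1 had an adjusted p of 0.0682. The second LINC00518 probe set lay below the mean of the negative controls on 3 of 3 SP arrays and 1 of 3 non-SP arrays. It varied between the non-SP arrays (5.30, 2.35 and 3.37), and its measured difference of -1.76 (SE 0.71) is limited by background. With the mean of both probe sets the gene's difference went from -3.51 (SE 0.14) to -2.63 (SE 0.35). Its call was lost in that setting (adjusted p = 0.122, range 0.00061 to 0.122 over 15 alternatives), which averages in the dim and variable second probe set. GJA1 passed without SP replicate 1 (adjusted p = 0.00928) and with array weights (adjusted p = 0.011; range 0.00928 to 0.389 over 16 alternatives).

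**Figure D1:**
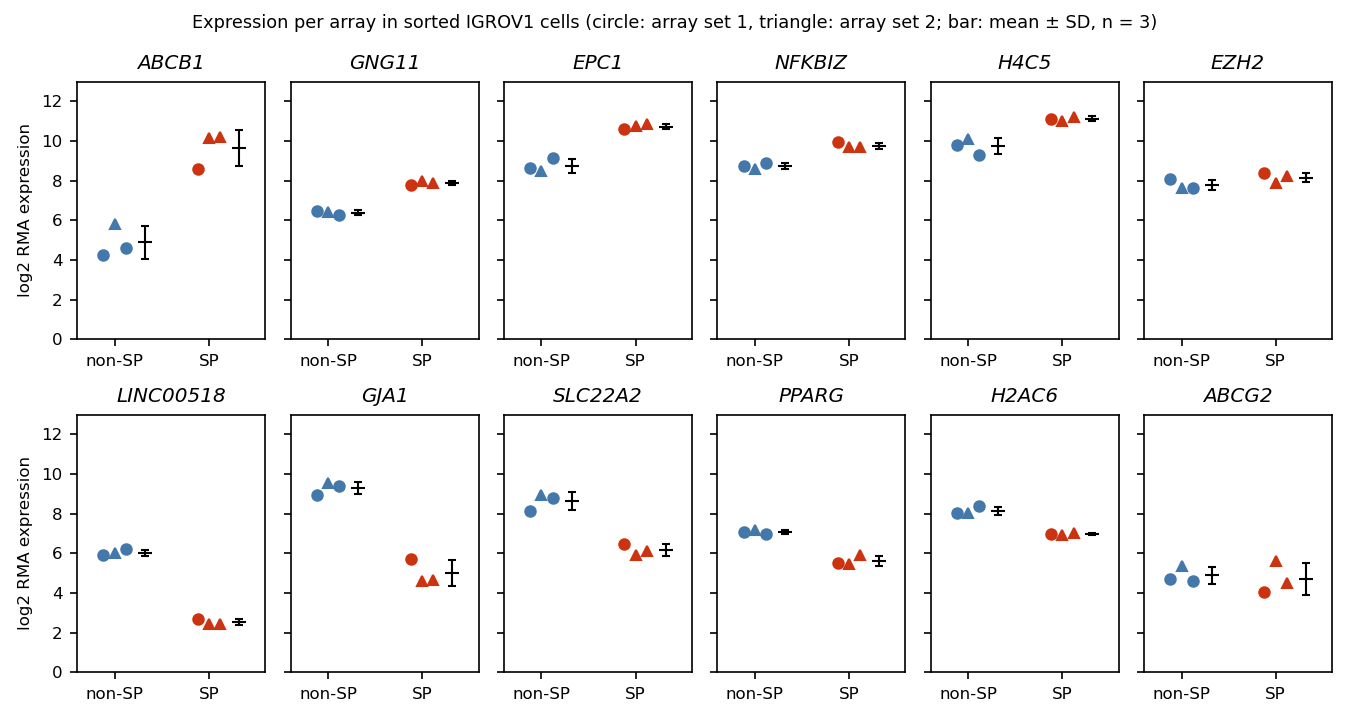
Log2 RMA expression (vertical axis) of 12 genes on each array, by sorted group (horizontal axis). Circles and triangles mark the 2 sets of arrays separated by the first principal component, and the bars show the mean and SD of 3 arrays; ABCB1 lay between 8.61 and 10.22 in SP and between 4.26 and 5.81 in non-SP samples, while LINC00518 lay between 2.42 and 2.70 in SP and between 5.90 and 6.20 in non-SP samples.

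Among genes above the median level, the 12 with the smallest unadjusted p in each direction all had groups that did not overlap, and 0 of these 24 genes passed the adjusted threshold. Besides ABCB1, those higher in SP samples included EPC1, a subunit of the NuA4 histone acetyltransferase complex (log2 difference 1.98, SE 0.19), SERPINB9, an inhibitor of granzyme B (1.52, SE 0.21), and GNG11, a G protein gamma subunit (1.49, SE 0.13). The replication-dependent histone gene H3C11, not a member of the histone list, had a difference of 1.46 (SE 0.18), SCAF4, which acts in transcription termination, 1.33 (SE 0.15), and the transcriptional repressor E2F6 1.06 (SE 0.14). NFKBIZ, an atypical IkB protein, had a difference of 1.02 (SE 0.14), and CARD16, LOC100505915, ARRDC3 and KCTD12 had differences between 0.96 and 1.21. Their adjusted p lay between 0.0694 for GNG11 and 0.158 for ARRDC3. The other GNG11 and CARD16 probe sets lay below the negative controls on all 6 arrays and decide nothing, while the lowest of the 4 EPC1 and 5 SCAF4 probe sets differed by -0.21 and -0.28. With the mean of its probe sets SCAF4 differed by 0.33 (SE 0.17, adjusted p = 0.75).

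Besides GJA1, those lower in SP samples included PRTFDC1, a relative of the purine salvage enzyme HPRT1 (log2 difference -2.50, SE 0.38), and SLC22A2, the organic cation transporter OCT2 (-2.46, SE 0.26). PTGDS, a prostaglandin D synthase, had a difference of -2.28 (SE 0.32), and UGT1A6, which conjugates small molecules to glucuronic acid, -2.13 (SE 0.29). The nuclear receptor gene PPARG had a difference of -1.44 (SE 0.16), and GADD45B, a stress-induced gene, also -1.44 (SE 0.18). CCBE1, SCGB1D2, LOC114224, H2AC6 and AMBP had differences between -1.84 and -1.07. Adjusted p lay between 0.0682 for GJA1 and 0.18 for PRTFDC1.

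Among the 14 genes of the Hoechst and drug efflux list, ABCB1 was the 1 member past the threshold adjusted over the list alone, and 0 members passed over all genes. ABCG2, the transporter most often tied to the side population phenotype, had a log2 level of 4.72 ± 0.80 (SD, n = 3) in SP cells and 4.90 ± 0.42 (SD, n = 3) in non-SP cells. Its difference of -0.18 had a 95% confidence interval of -1.18 to 0.82, and its sign turned without SP replicate 1 (0.16) and without non-SP replicate 2 (0.06). ABCC5 differed by 0.52 (SE 0.20), ABCC2 by 0.40 (SE 0.17) and ABCC11 by -0.28 (SE 0.14), and the mean of its probe sets turned ABCC5 to -0.08. ABCC11 was dim, with means of 3.13 in SP and 3.41 in non-SP cells, below the first quartile of the arrays. The list as a whole was shifted up (median 0.14, camera adjusted p = 0.0144; 0.09 to 0.28 with 1 sample left out). The shift was lost with an estimated correlation (adjusted p = 0.665), with the array sets as a block (adjusted p = 0.105), without ABCB1 (adjusted p = 0.108), with the mean of a gene's probe sets (adjusted p = 0.07), and without SP replicate 2, SP replicate 3 or non-SP replicate 3 (adjusted p = 0.0851, 0.0702 and 0.133); over 16 alternatives that keep the preset correlation the adjusted p ranged from 0.00215 to 0.133.

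Genes of the NF-kB and inflammatory list were shifted up in SP cells, with 24 of 29 measured members at a difference above 0 and a median of 0.30 (camera adjusted p = 2.19e-05). With an estimated correlation the list did not pass (adjusted p = 0.287). Adjusted over the list alone, 3 members were higher and 0 lower: NFKBIZ, the neutrophil chemokine CXCL2 (log2 difference 1.10, SE 0.20) and TNFAIP3, the deubiquitinase A20 that limits NF-kB signalling (1.13, SE 0.23). CXCL3 differed by 0.72 (SE 0.24). With the mean of their probe sets CXCL2 and TNFAIP3 each differed by 0.72 (SE 0.54 and 0.40, limma adjusted p = 0.847 and 0.757). NFKBIZ then differed by 1.04 (SE 0.20, limma adjusted p = 0.272). The list's median was 0.20 and 0.18 within the 2 sets of arrays.

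Histone genes, 25 of them core and 5 linker histones, were shifted up as a list (median 0.40, 24 of 30 members above 0, camera adjusted p = 4.08e-05), but the call was lost with an estimated correlation (adjusted p = 0.665) and members moved in both directions. Adjusted over the list alone, 8 were higher and 3 lower, and of the 8, 5 encode core and 3 linker histones. H4C5 differed by 1.37 (SE 0.21) and H2BC9 by 1.11 (SE 0.23), whereas H2BC21 differed by -1.14 (SE 0.12) and H2AC6 by -1.16 (SE 0.14); the remaining gene on the lower side was H2BC4 at -1.08 (SE 0.28). H2BC21, H2AC6 and H2BC4 are known to be made in part as polyadenylated RNA outside S phase, as is H2BC5, which differed by 1.22 (SE 0.33). Within the 2 sets of arrays the list's median was 0.65 and 0.34. Over 15 alternatives that keep the preset correlation it ranged from 0.30 (array weights) to 0.86 (only genes above the median level).

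Homologous recombination and Fanconi anaemia genes were shifted up (median 0.20, 21 of 29 members above 0, camera adjusted p = 0.00294), but not with an estimated correlation (adjusted p = 0.287). The estimate for this list was -0.00101, below the preset 0.01, so the call was not lost to a higher correlation among its genes. Loss of a call with an estimated correlation is thus not by itself evidence that the genes of a list are correlated. BLM, a DNA helicase, differed by 0.90 (SE 0.13) and FANCB by 0.61 (SE 0.13), and these 2 members were higher and 0 lower adjusted over the list alone. MRE11 differed by 0.63 (SE 0.17) and FANCL by -0.54 (SE 0.16). The G1/S genes, active around the start of DNA replication, were also shifted up (median 0.10, 29 of 41 members above 0, camera adjusted p = 0.00266), but not with an estimated correlation (adjusted p = 0.673), and 1 member, BLM, passed adjusted over the list alone. EXO1 differed by 0.81 (SE 0.21), HELLS by 0.53 (SE 0.19) and CLSPN by 0.47 (SE 0.20). Without non-SP replicate 2 the medians of the homologous recombination and G1/S lists were 0.09 and 0.05 (adjusted p = 0.0607 and 0.62), and the adjusted p of the G1/S list was 0.052 without SP replicate 1 and 0.171 with array weights. With 1 sample left out the 2 medians ranged from 0.09 to 0.26 and from 0.05 to 0.21, and the G1/S median was 0.01 with array weights. Over 15 alternatives that keep the preset correlation the adjusted p ranged from 0.000219 to 0.0607 and from 1.63e-06 to 0.62.

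Nuclear genes of the respiratory chain and ATP synthase were shifted down as a list, with 58 of 67 members below 0 and a median of -0.09 (camera adjusted p = 0.00366). With an estimated correlation the list did not pass (adjusted p = 0.665). With each array centred on its median, the list's median was -0.06 (camera adjusted p = 0.0114). NDUFB10 differed by -0.40 (SE 0.18), NDUFA5 by -0.37 (SE 0.15), NDUFB4 by -0.33 (SE 0.12) and ATP5MC2 by -0.32 (SE 0.16), and 0 members passed adjusted over the list alone or over all genes. The mean of its probe sets turned NDUFA5 to 0.07, its other probe set lying below the negative controls on all 6 arrays. The shift was lost with the array sets as a block (adjusted p = 0.0522) and without non-SP replicate 3 (adjusted p = 0.0843; range 0.000362 to 0.0843 over 15 alternatives that keep the preset correlation).

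The unfolded protein response (median 0.18), heat shock (median 0.08) and ribosome biogenesis (median 0.06) lists each had a camera adjusted p of 0.0402, in the upward direction, with 0 members past the threshold adjusted over the list alone. With an estimated correlation none passed (adjusted p = 0.87, 0.665 and 0.78), and with 1 sample left out the medians ranged from 0.06 to 0.37, from 0.03 to 0.11 and from 0.01 to 0.15. DDIT4, an inhibitor of mTORC1 signalling, differed by 0.37 (SE 0.12), the chaperone genes HSPH1 by 0.56 (SE 0.12) and HSPA6 by 0.95 (SE 0.29), and the ribosome assembly gene RRS1 by 0.45 (SE 0.16). With the array sets as a block the adjusted p were 0.769, 0.0522 and 0.434, and the median of the unfolded protein response list turned to -0.04. Each of these 3 lists also lost its call when SP replicate 2 was left out (adjusted p = 0.431, 0.102 and 0.431), when SP replicate 3 was (0.445, 0.151 and 0.231) and when non-SP replicate 1 was (0.425, 0.0871 and 0.216). Without non-SP replicate 3 the adjusted p of the unfolded protein response and ribosome biogenesis lists were 0.349 and 0.254, and without non-SP replicate 2 that of the heat shock list was 0.254. They passed in 5, 4 and 6 of the 15 alternatives that keep the preset correlation, with ranges of 5.13e-05 to 0.769, 0.00831 to 0.254 and 0.000412 to 0.434.

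In all, 9 of 38 lists passed camera with its preset correlation, and 0 passed with an estimated correlation or with fry, a rotation test of whether a list's genes move one way on balance (smallest adjusted p = 0.287 and 0.129). With the preset correlation, camera also called 2 to 9 lists in each of the 9 other ways of parting the samples into 3 and 3. The mixed form of fry, which tests for change in either direction, passed for 5 lists: NF-kB, histones, homologous recombination, Wnt and pluripotency (adjusted p = 9.03e-05, 0.000505, 0.000482, 0.00335 and 0.034).

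**Figure D2:**
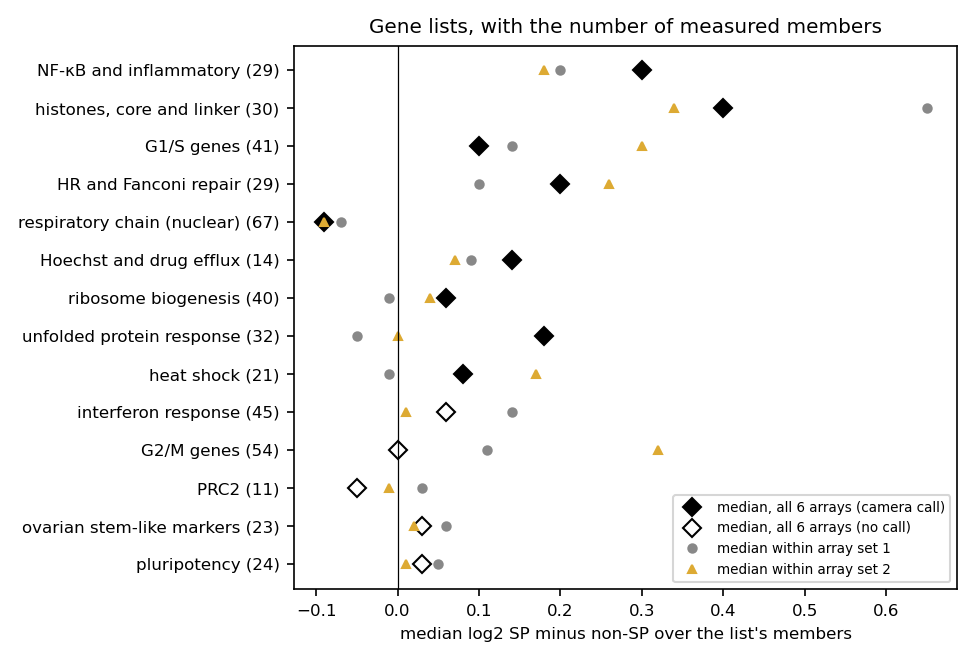
Median log2 difference, SP minus non-SP, over the measured members of 14 gene lists (horizontal axis, log2 units; members in brackets). Diamonds give the median over all 6 arrays, filled where camera with its preset correlation passed, and small symbols give it within each of the 2 sets of arrays; the histone list had the median furthest from 0 among the lists drawn, 0.40, and the unfolded protein response list lay at 0.18 overall but at -0.05 and 0.00 within the sets.

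Of 23 measured genes used as markers of stem-like ovarian cancer cells, 0 passed the threshold adjusted over the list alone or over all genes. PROM1 (CD133) had a log2 level of 10.43 ± 0.19 (SD, n = 3) in SP and 10.17 ± 0.35 (SD, n = 3) in non-SP cells, a difference of 0.26 with a 95% confidence interval of -0.24 to 0.75. CD44 differed by 0.13 (interval -0.29 to 0.56), with 8 of its 13 probe sets in that direction. ALDH1A1 differed by -0.21 (interval -1.57 to 1.16) and KIT by 0.08 (interval -0.97 to 1.14), and the signs of both turned without SP replicate 3 (0.44 and -0.29), that of KIT also without non-SP replicate 1 (-0.27). KIT was dim, with means of 3.87 in SP and 3.78 in non-SP cells, below the first quartile of the arrays, so its difference says little. ALDH1A3, another aldehyde dehydrogenase, differed by -1.89 (SE 0.69, adjusted p = 0.677), ENG by -0.31 (SE 0.12), MYD88 by -0.77 (SE 0.32) and SOX9 by 0.96 (SE 0.49). Over the 23 marker genes the median was 0.03 (camera adjusted p = 0.793), and over 19 aldehyde dehydrogenases it was -0.12 (adjusted p = 0.369). With the array sets, read from the same values, as a block ALDH1A3 passed at -2.50 (SE 0.17, adjusted p = 0.0384, range 0.0384 to 1 over 16 alternatives).

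EZH2, the histone H3 lysine methyltransferase of Polycomb repressive complex 2 (PRC2), had a log2 level of 8.16 ± 0.25 (SD, n = 3) in SP and 7.79 ± 0.27 (SD, n = 3) in non-SP cells. Its difference of 0.38 (SE 0.19) had a 95% confidence interval of -0.09 to 0.84 and an adjusted p of 0.803. EED differed by 0.20 (SE 0.12), AEBP2 by 0.13 (SE 0.12) and EZH1 by -0.31 (SE 0.30). The median over the 11 PRC2 genes was -0.05 while the direction of the camera test was upward (adjusted p = 0.793). Among 24 pluripotency genes, MYC differed by 0.65 (SE 0.16), KLF4 by 1.01 (SE 0.33), KLF5 by 0.42 (SE 0.15) and LIN28A by -0.61 (SE 0.21), with 0 members past the threshold adjusted over the list alone, a median of 0.03 and a camera adjusted p of 0.369. LIN28A was dim, with means of 3.42 in SP and 4.03 in non-SP cells.

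The arrays also differed in a way that cut across the sort. The first principal component held 45.8% of the variance and set non-SP replicate 1, non-SP replicate 3 and SP replicate 1 (set 1) apart from non-SP replicate 2, SP replicate 2 and SP replicate 3 (set 2). The asparagine synthetase gene ASNS had log2 levels of 9.60, 9.90 and 9.78 on the arrays of set 1 and of 12.64, 12.39 and 12.43 on those of set 2, and the median level of the unfolded protein response list was 9.46 to 9.51 in set 1 and 10.28 to 10.39 in set 2. Because set 1 holds 1 SP sample and set 2 holds 2, the SP minus non-SP difference was also taken within each set, where 1 of the groups has a single sample. For ABCB1 it was 4.19 and 4.38, with 4.28 (SE 0.14) and an adjusted p of 0.00142 when the set, read from the same values, entered as a block (range 0.00142 to 0.455 over 16 alternatives). For LINC00518 it was -3.35 and -3.57, for GJA1 -3.42 and -4.93, for EZH2 0.51 and 0.41, and for ABCG2 -0.63 and -0.31.

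RNA quality controls differed between the sorted groups by less than the spread between arrays. The log2 3' minus 5' signal of ACTB was 2.34 ± 0.22 (SD, n = 3) in SP and 2.29 ± 0.26 (SD, n = 3) in non-SP samples (two-sided exact permutation p = 0.9). That of GAPDH was 0.12 ± 0.07 (SD, n = 3) and 0.18 ± 0.16 (SD, n = 3) (exact permutation p = 0.6). With 3 arrays against 3 the smallest p this test allows is 0.1. Across the sets of arrays, the ACTB value lay between 2.02 and 2.29 in set 1 and between 2.46 and 2.55 in set 2.

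**Figure D3:**
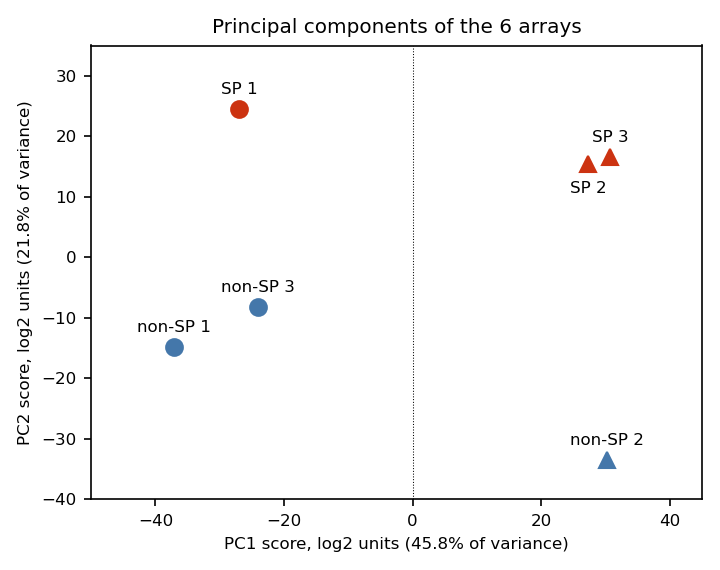
Scores of the 6 arrays on the first (horizontal axis, 45.8% of variance) and second (vertical axis, 21.8% of variance) principal components, in log2 units, with circles for array set 1 and triangles for array set 2. Both groups have arrays on each side of 0 on the first component, while on the second the 3 SP arrays lie between 15.39 and 24.51 and the 3 non-SP arrays between -33.53 and -8.17.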

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

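The array set as a block, the ACTB covariate and the Hoechst efflux list without ABCB1 were chosen after seeing the data. The set was read from the same values, so adjusted p with it as a block may be too small. LINC00518 stayed past the threshold in 14 of 15 alternatives (log2 difference -3.60 to -2.63), including each of the 6 that leave out a sample; it is not among the genes above the median level. The number of genes changed, 1, became 3 with the replicate block (1 higher, 2 lower), 0 with the mean of all of a gene's probe sets (0 lower, 1515 genes at an unadjusted p under 0.05), 0 with only genes above the median level (0 lower, 702 genes at an unadjusted p under 0.05), 12 with array weights (4 higher, 8 lower), 5 with the array set as a block (1 higher, 4 lower) and 3 with the ACTB 3' minus 5' signal as a covariate (1 higher, 2 lower). Leaving out each sample in turn gave 1 to 2 genes changed and 1 to 2 lower, the 2 being GJA1 and LINC00518 without SP replicate 1. ABCB1 was above 0 in each of its 16 alternatives (3.62 to 5.30) and passed in 3: array weights (adjusted p = 0.038), the array set as a block (0.00142) and the ACTB covariate (0.00332). These 3 are not independent of each other. The ACTB signal was higher on all arrays of set 2. The lowest weights went to non-SP replicate 2 (0.54) and SP replicate 1 (0.56), each the only array of its group in its set. Whether the replicate numbers pair the samples is not established: deviations of same-numbered samples correlated at 0.449, 0.381 and -0.212. The replicate block added RUNDC3B and SFRP1 to the calls and lost the heat shock list (adjusted p = 0.0793; 0.00831 to 0.254 over 15 alternatives that keep the preset correlation). The 9 lists became 0 with a correlation estimated from the data and 0 with fry, and 6 to 10 under the other alternatives. The histone and NF-kB lists passed camera in 15 of 15 alternatives that keep the preset correlation. With that correlation camera also called 2 to 9 lists in each of the 9 other splits of the samples. Passing in these alternatives thus does not show that a shift belongs to the sort. Signs turned for ABCG2 with array weights (0.17), ALDH1A1 with the array set as a block (0.16), KIT with the array set as a block (-0.18) and with the ACTB covariate (-0.02), and, with the mean of probe sets, ABCC5 (-0.08) and NDUFA5 (0.07). Of the list medians, the unfolded protein response list turned to -0.04 and the stem-like marker list to -0.04 with the array set as a block, and with array weights the G2/M list stood at -0.17 and the PRC2 list at -0.15, with their tests turned downward. Leaving out each sample in turn moved ABCG2 from -0.62 to 0.16, ALDH1A1 from -0.72 to 0.44, KIT from -0.29 to 0.42, and the medians of the G2/M, PRC2 and stem-like marker lists from -0.19 to 0.17, from -0.14 to 0.06 and from -0.02 to 0.16. The cause was not tested for most of these, except that fewer genes were tested above the median level (9887). Array set 2 holds 2 SP samples and 1 non-SP sample, and the unfolded protein response list was higher there by 0.54. That imbalance raises the list's median over all 6 arrays, which was 0.18. Within the sets, where 1 group has a single sample, the median was -0.05 and 0.00. The G2/M list was shifted by -0.46, so the same imbalance lowers its median of 0.00 over all 6 arrays. Signal over background limits the dim genes: in SP cells LINC00518 lay at 2.52, below the negative controls, so its fold is a lower bound.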

Other observations

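The tests of the array sets, of RNA integrity, of ABCB4 as a paralog, of both gains as the sole source of the ABCB1 difference and of cycling cells were chosen only after the results were seen. The counts of splits were planned, and the test of ABCB1's neighbours was set before their values were seen.

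Interferon response genes had a median difference of 0.06 over 45 members and missed the camera threshold (adjusted p = 0.0737). The list passed with the array sets as a block (camera adjusted p = 0.0133), without SP replicate 2 (0.0143) and without non-SP replicate 3 (0.0227). Over 15 alternatives that keep the preset correlation the adjusted p ranged from 0.0133 to 0.57. With 1 sample left out the median ranged from 0.01 to 0.13. The antiviral factor SAMD9 differed by 1.04 (SE 0.29), its neighbour and relative SAMD9L by 0.68 (SE 0.16) and OAS1, a sensor of double-stranded RNA, by 0.70 (SE 0.18), whereas the immunoproteasome subunit PSMB8 differed by -0.52 (SE 0.14). Of 25 cholesterol and fatty acid synthesis genes, 18 were below 0 (median -0.13, adjusted p = 0.124), among them EBP (-0.41, SE 0.13), DHCR7 (-0.27, SE 0.11) and the desaturase SCD (-0.23, SE 0.11), while STARD4, a cholesterol carrier, differed by 0.67 (SE 0.20). Of 53 cytosolic ribosomal protein genes, 44 were below 0 with a median of -0.04 (adjusted p = 0.151, and 0.00377 with an intensity trend and robust prior; range 0.00377 to 0.496 over 15 alternatives that keep the preset correlation), for example FAU at -0.19 (SE 0.11) and RPL36 at -0.17 (SE 0.11). With each array centred on its median, the ribosomal protein median was -0.01 (camera adjusted p = 0.349). The count below 0 thus depends in part on the level to which the arrays are set. With an estimated correlation the adjusted p of the interferon, cholesterol and ribosomal protein lists were 0.665, 0.665 and 0.673.

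Markers of other cell types gave 0 calls with camera or with directional fry (smallest adjusted p = 0.082) in a family of 5 lists, while the mixed form of fry, for change in either direction, passed for the endothelial and leukocyte markers (adjusted p = 0.0487 each). The endothelial markers had a median of -0.15 (camera adjusted p = 0.195), the erythroid markers -0.17 (0.427), the fibroblast markers -0.05 (0.958), the leukocyte markers 0.04 (0.427) and the mesothelial markers 0.02 (0.495). Of the 13522 probe sets with several genes or unnamed here, 0 passed the threshold in limma, with 1157 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0706.

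The 6 arrays fell into 2 sets that cut across the sort, and the split of the samples along these sets called 1054 genes and 9 lists, many times the 1 gene of the real split. This points to a structure of the samples but is no separate evidence for it, since the sets were read from the same genes. Among the 10 splits of 6 samples into 3 and 3, the real one included, 2 gave as many genes as the real split (1 gene; highest other 1054) and 2 gave as many lists (9; highest other 9). The split along the sets was the other one in both counts, and 10 splits are too few for a share under 0.05. With the preset correlation, camera called 2 to 9 lists in each of the 9 other splits. RNA integrity stays open: the ACTB 3' minus 5' signal was higher on all 3 arrays of set 2, while that of GAPDH overlapped between the sets (mean difference 0.08), which decides nothing with 6 arrays. A different growth or nutrient state of the cultures is a hypothesis that stays open too: the unfolded protein response list, which holds the amino acid response genes ASNS, PHGDH and SLC7A11, was shifted by 0.54 between the sets (random lists -0.12 to 0.15) and the G2/M list by -0.46 (random lists -0.11 to 0.13). This test was run on arrays parted by their own expression, and the labels give no culture, day or batch to set it against.

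ABCB1 differed by 4.78 between SP and non-SP cells, and the gate itself selects for dye export, so the difference may reflect that selection, an explanation that was not tested. Signal shared with the paralog ABCB4 is argued against, since ABCB4 differed by 0.32 with a 95% interval of -0.33 to 0.98. A gain of the chromosomal segment around ABCB1 in SP cells could add to it. The 10 nearest measured neighbours other than ABCB4 and RUNDC3B had a median difference of 0.21. That median lay at the 99.6th percentile of random lists (95% of them between -0.19 and 0.14), with CROT at 1.00 (SE 0.41) and DBF4 at 0.50 (SE 0.20). ABCB4, left out of these 10, is also a neighbour, with the difference of 0.32 given above. A gain spanning these 10 neighbours is argued against as the sole source, because 8 of the 10, all above the negative controls, had an upper 95% bound below 1.41, the lower bound of the ABCB1 probe set with the smaller difference; CROT, with an upper bound of 1.99, did not. A gain limited to ABCB1 and RUNDC3B, which overlaps it in the annotation, stays open. The RUNDC3B probe set above the negative controls on all 6 arrays differed by 1.45 (SE 0.39), with an upper bound of 2.39 that lies above 1.41 but below the 3.44 of the main ABCB1 probe set. The other, with a measured difference of 3.18 (adjusted p = 0.184), lay below the controls on 1 of 3 non-SP arrays, so that it gives only a lower bound of 3.11. Transcription across the locus was not tested.

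The G1/S, histone and homologous recombination lists were shifted up in SP cells with camera's preset correlation. Whether the 2 sets of arrays are the cause stays open. With the sets as a block 3 of 3 lists passed camera (adjusted p = 1.63e-06, 1.92e-07 and 0.000219). Over 15 alternatives each that keep the preset correlation, the ranges were 1.63e-06 to 0.62, 1.92e-07 to 0.00852 and 0.000219 to 0.0607. The medians within the 2 sets were 0.14 and 0.30, 0.65 and 0.34, and 0.10 and 0.26. These calls cannot exclude the sets, because the block was read from the same values. With the preset correlation camera also called 2 to 9 lists in each of the 9 other splits. A larger share of cycling cells in the SP gate stays open: the G2/M list had a median of 0.00 over all 6 arrays (adjusted p = 0.201), but 0.11 and 0.32 within the sets, where 1 of the groups has a single sample and the sets come from the same data, so that these values decide nothing. The G2/M list passed with the sets as a block (camera adjusted p = 1.75e-09, range 1.75e-09 to 0.677 over 15 alternatives that keep the preset correlation). The estimated correlation was applied only without the block, where the list did not pass with it (adjusted p = 0.87). CDK1 differed by 0.64 (SE 0.20) and KIF20B by 0.69 (SE 0.21). The G2/M median stood at -0.15 without SP replicate 1 and at -0.19 without non-SP replicate 2, and at 0.13, 0.10, 0.17 and 0.13 without SP replicate 2, SP replicate 3, non-SP replicate 1 and non-SP replicate 3, where the list passed upward (adjusted p = 0.0324, 0.0228, 0.00737 and 0.00058). None of the 3 lists, nor the G2/M list, passed with an estimated correlation in the fit without the block, so the shifts in that fit stay open. With the block only the preset correlation was used, which leaves the shifts there open too. The DNA content of the sorted cells was not analysed here.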
